A study of Mus musculus with 13 samples.

How the data were processed

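Whole brains of mouse embryos at embryonic day 18.5 were profiled on Affymetrix mouse genome arrays, with 1 embryo per array. The 13 arrays held 6 wild-type embryos and 7 without Meg3, drawn from 5 litters, and the genotype and replicate number of each were taken from the sample titles. The litter of each embryo was read from the leading number of its embryo label. Litter 148 held 1 knock-out embryo, litter 219 held 2 wild-type and 1 knock-out, litter 238 held 1 wild-type and 2 knock-out, litter 250 held 2 of each, and litter 262 held 1 of each. The embryos are stated to be biological replicates. Their sex was not given in the sources used here, and is read from Xist and Eif2s3y below.

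Per the labels' protocols, total RNA was extracted with a lipid tissue kit and 5 µg of it was turned into biotinylated cRNA with the one-cycle labelling procedure. The deposited values are linear probe set intensities, not log-transformed. The software, the summary method and the scaling were not given in the sources used here. In the deposited table the values below a fixed bound lay within 0.05 of a whole multiple of 1 step per array, and the mean signal after trimming 2% at each end was 5000.02 to 5000.03 steps. Such values would arise from a trimmed mean scaled to about 500 on each array before 1 factor per array, which ranged from 0.908 to 1.08, was applied, though no source states it. The number of arrays limits the precision, and no read depth applies.

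The table held 45101 probe sets, of which 64 were Affymetrix controls. Of the remaining 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 were unnamed here. The Entrez identifiers of 34741 of the named probe sets were found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed an update. That table was used only for names and for which genes neighbour each other, because no genome build was given for the array values. The named probe sets represented 18193 genes.

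For the main comparison, intensities were turned into log2(signal + 16), so that fold changes of weak genes are understated. Probe sets with a mean log2 value above the 40th percentile of all non-control probe sets were kept, which corresponds to a signal of 56.9. For each gene the probe set with the highest mean was used, and this left 12920 genes. Among the genes kept, 6200 had more than 1 probe set above the filter, and named genes whose probe sets differ in sign are given with their range. Knock-out and wild-type arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No litter term was in this fit. Single values were also compared with two-sided exact permutation tests over all 1716 ways to split the 13 arrays, whose smallest possible p is 0.00117. These splits ignore litter, so their p does not allow for variation that littermates share. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

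Fixed before the data were examined were 22 gene lists with 417 entries, of which 393 had a named probe set. They covered the imprinted Dlk1-Dio3 genes and the genes flanking them, VEGF and angiogenesis, endothelial and mural cells, hypoxia, p53 targets, the cell cycle, and Notch and TGF-beta signalling. Others covered neurons, neural progenitors, astrocytes, oligodendrocytes, microglia, red cells, choroid plexus, meninges, neighbouring tissues, other imprinted genes, immediate early genes and sex-linked genes. Shifts of lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, two-sided, and again with an estimated correlation, each adjusted over the lists. Camera compares a list with the other genes, so its direction can differ from the sign of the list's own mean. The theme of the VEGF and angiogenesis list stands in the title of the series, so that list is not independent evidence of a direction.

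The genes named in the text follow a rule that was also fixed beforehand. It takes every measured member of the Dlk1-Dio3 imprinted list and every Meg3 probe set, and Vegfa, Flt1, Kdr, Nrp1, Hif1a and Notch1 whatever their p. It adds up to 12 genes per direction with the largest changes among those past the threshold that have the same sign in each of the 4 litters with both genotypes. From each list it takes up to 4 members past the threshold by smallest p, or, where none passed, the 2 with the smallest p. Any gene outside this rule is said to have been chosen after its values were seen.

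The gene test was run on simulated data for this comparison, with 200 of 12920 genes changed in each of 10 draws and the residuals of the real arrays shuffled between arrays. It recovered 39.3% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 98.9% of those changed 4-fold, with 3.49% false calls. Where fewer genes change, the adjustment over all genes is stricter. The real comparison called 3 genes, so these rates overstate what it could recover. With independent noise instead, all 20 of 20 lists of 25 random genes shifted by 0.5 (log2) were called, and 0 of 380 unshifted lists. That simulation holds no genes that vary together, so it does not give the rate of false calls for the real lists. Other splits of the real arrays, described below, had a median of 3 lists past the threshold.

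Litter was checked as a source of shared variation through the correlation, across genes, of the arrays' deviations from their group means. Pairs from the same litter and of different genotype had a median correlation of 0.12 (9 pairs, -0.11 to 0.58), and pairs from different litters and of different genotype a median of -0.03 (33 pairs, -0.36 to 0.40). All 13 pairs from the same litter had a median of 0.08, down to -0.58 for wild-type 1 and 2. Alternatives fixed beforehand changed the filter, the normalization between arrays, the pseudocount, the variance model, the choice of probe set, the treatment of litter and of the replicate numbers, and the threshold. They also added Xist level or the 3' to 5' ratio of control probe sets as a covariate, and left out each litter and each array in turn. A further 4 alternatives on arrays, litters and scaling were chosen after seeing the data. Probe sets with several gene symbols were not analysed here.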

Results

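Expression was measured in whole brains of mouse embryos at embryonic day 18.5 that lacked Meg3 or were wild-type. Meg3 is a maternally expressed long non-coding RNA of the imprinted Dlk1-Dio3 cluster. There were 7 knock-out and 6 wild-type arrays, each from 1 embryo, and the title of the series places the question in the expression of angiogenic genes. Correlations between arrays over the 12920 genes tested ranged from 0.894 to 0.990. RNA quality, read from the 3' to 5' ratio of the Actb control probe sets, stood apart in wild-type 2 (ratio 2.92) and knock-out 1 (ratio 1.81), against 1.32 to 1.495 in the other 11 arrays.

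Meg3 was almost lost from knock-out brains. Its signal was 378 ± 106 (SD, n = 7) in knock-out and 4955 ± 1374 (SD, n = 6) in wild-type brains, a fall by 12.5-fold on the log2(signal + 16) scale (log2 change -3.64 ± 0.20 SE, limma adjusted p = 1.25e-07). All 11 of 11 Meg3 probe sets were lower past the threshold when every probe set was tested, with folds of at least 5.71. The largest folds are set by the pseudocount, because some of these probe sets had knock-out signals below the filter. No knock-out array overlapped a wild-type array (exact permutation p = 0.00117, the smallest that splits ignoring litter allow). Within litters the log2 difference was -3.45 in litter 219, -4.30 in litter 238, -3.65 in litter 250 and -3.79 in litter 262. Which part of Meg3 was removed was not given in the sources used here, so the place of each probe set relative to the deletion is unknown.

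The 2 neighbouring maternally expressed non-coding RNAs of the cluster fell with Meg3. Rian, which hosts small nucleolar RNAs, fell from 6778 ± 2191 (SD, n = 6) to 389 ± 127 (SD, n = 7), with a log2 change of -4.05 ± 0.29 SE (limma adjusted p = 2.67e-06). Mirg, a microRNA host transcript, fell from 336 ± 80.4 (SD, n = 6) to 49.8 ± 24.0 (SD, n = 7), with a log2 change of -2.46 ± 0.23 SE (limma adjusted p = 6.33e-05). All 4 of 4 Rian and 2 of 2 Mirg probe sets were lower past the threshold. Dlk1, the paternally expressed gene of the cluster that encodes a Notch-related membrane protein, did not pass the test. Its signal was 1182 ± 279 (SD, n = 7) in knock-out and 1131 ± 381 (SD, n = 6) in wild-type brains, with a log2 change of 0.09 (95% interval -0.34 to 0.53, limma adjusted p = 1.00), and its second, weaker probe set had one of -0.03. Dio3os, an antisense transcript of the cluster, lay below the filter at signals of 27.2 and 28.8, and Rtl1 and Dio3 had no named probe set in the annotation used. Of the 4 tested members of the imprinted list, 3 were lower past the threshold both over all genes and adjusted over the list alone. The list shifted down (camera adjusted p = 3.46e-33, adjusted p = 3.02e-05 with an estimated correlation).

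**Figure D1:**
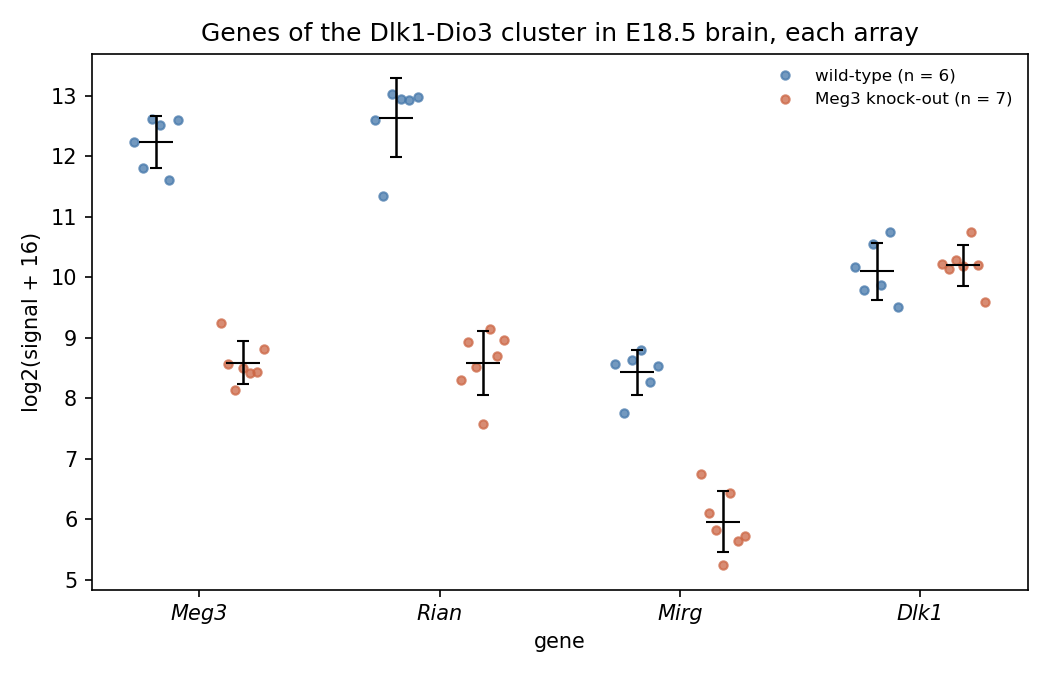
Log2(signal + 16) of Meg3, Rian, Mirg and Dlk1 on the vertical axis, 1 point per array for 6 wild-type and 7 Meg3 knock-out brains, with group mean and SD as black bars. The groups do not overlap for Meg3, Rian and Mirg, while Dlk1 values of both groups cover the same range.

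The genes flanking the cluster on either side had small higher values in knock-out brains. Of 16 tested members 15 had a higher and 1 a lower mean, the mean log2 change was 0.10, and 0 passed the threshold over all genes or adjusted over the list alone. Wars, a tryptophanyl-tRNA synthetase, had a log2 change of 0.29 ± 0.16 SE, and Rcor1, a transcriptional corepressor, one of 0.24 ± 0.16 SE. The list did not pass (camera adjusted p = 0.158, and 0.732 with an estimated correlation). Among the alternatives fixed beforehand it passed with litter as a block (adjusted p = 0.0377), without litter 219 (0.0178) and without wild-type 1 (0.0314). With an estimated correlation it passed in 0 of 37 (lowest adjusted p = 0.313). An exact permutation test of its mean gave p = 0.0198 (0.218 adjusted over the lists), and its mean differed by 0.16, 0.09, 0.10 and 0.06 in litters 219, 238, 250 and 262. After median centring its mean was -0.10, when the median of all genes was -0.15.

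Across the genome, Meg3, Rian and Mirg were the 3 genes lower past the threshold among 12920 tested, and 0 genes were higher. At an unadjusted limma p under 0.05 there were 255 genes, 222 with a higher and 33 with a lower mean in knock-out brains, where chance alone gives 646. Ordinary least squares without moderation gave 248 such genes and the same counts of 0 and 3 past the threshold. Which genes reached that p, and in which direction, depended on the scaling. Quantile normalization gave 49 higher and 304 lower, and median centring 22 higher and 737 lower, as the median log2 change over all genes went from 0.04 to -0.03 and to -0.15. With the array factor removed, an alternative chosen after seeing the data, there were 115 higher and 116 lower at a median of -0.01. Without litter 238, or without its wild-type 3 array, the count of higher genes was 1, which was Serpina3n, an acute-phase serine protease inhibitor named here after its values were seen. Groups did not overlap for 10 genes, 7 of them higher, where chance gives 15.1 (0.117% of genes).

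Vegfa, the main growth factor for blood vessels, had a higher signal in each knock-out array than in any wild-type array. Its mean was 767 ± 141 (SD, n = 7) against 564 ± 44.2 (SD, n = 6), a ratio of 1.34-fold on the log2(signal + 16) scale (log2 change 0.42, 95% interval 0.17 to 0.67). The single-value exact permutation p was 0.00117, the smallest that splits ignoring litter allow. The adjusted p over all genes was 1.00 in limma, so Vegfa did not pass. Median centring took its log2 change to 0.22 ± 0.12 SE, the lowest of 37 alternatives. Within litters its log2 difference was 0.25, 0.39, 0.41 and 0.20 in litters 219, 238, 250 and 262, and its second probe set had a log2 change of 0.38. On the probe sets used, the 95% intervals of the VEGF receptors held both signs. Kdr had a log2 change of 0.34 (95% interval -0.14 to 0.82), Flt1 of 0.14 (-0.26 to 0.54) and the co-receptor Nrp1 of 0.20 (-0.22 to 0.63). Hif1a, the oxygen-regulated transcription factor, stood at 0.01 (-0.23 to 0.25) and the receptor Notch1 at -0.01 (-0.50 to 0.49). All these have a limma adjusted p of 1.00. The 4 Flt1 probe sets ranged from 0.14 to 0.46, those of Nrp1 from 0.13 to 0.68 and those of Notch1 from -0.01 to 0.09. The highest Flt1 probe set had an SE of 0.16 and a limma adjusted p of 0.884 when every probe set was tested.

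The angiogenesis list as a whole did not shift. Of its 40 tested genes 27 had a higher and 13 a lower mean, 0 passed the threshold over all genes, and 0 passed adjusted over the list alone, where the smallest adjusted p was 0.106. After Vegfa the smallest p belonged to Adm, which encodes the vasoactive peptide adrenomedullin, with a log2 change of 0.30 ± 0.12 SE. The mean log2 change of the list was 0.06 (camera adjusted p = 0.750, and 0.995 with an estimated correlation), and an exact permutation test of the list's mean gave p = 0.529. Within litters the list mean differed by 0.22, -0.07, 0.07 and -0.01 in litters 219, 238, 250 and 262. Under quantile normalization and median centring the mean turned to -0.05 and -0.14, beside shifts of all genes to -0.03 and -0.15. Being taken from the theme of the series, the list is not independent evidence of its direction.

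**Figure D2:**
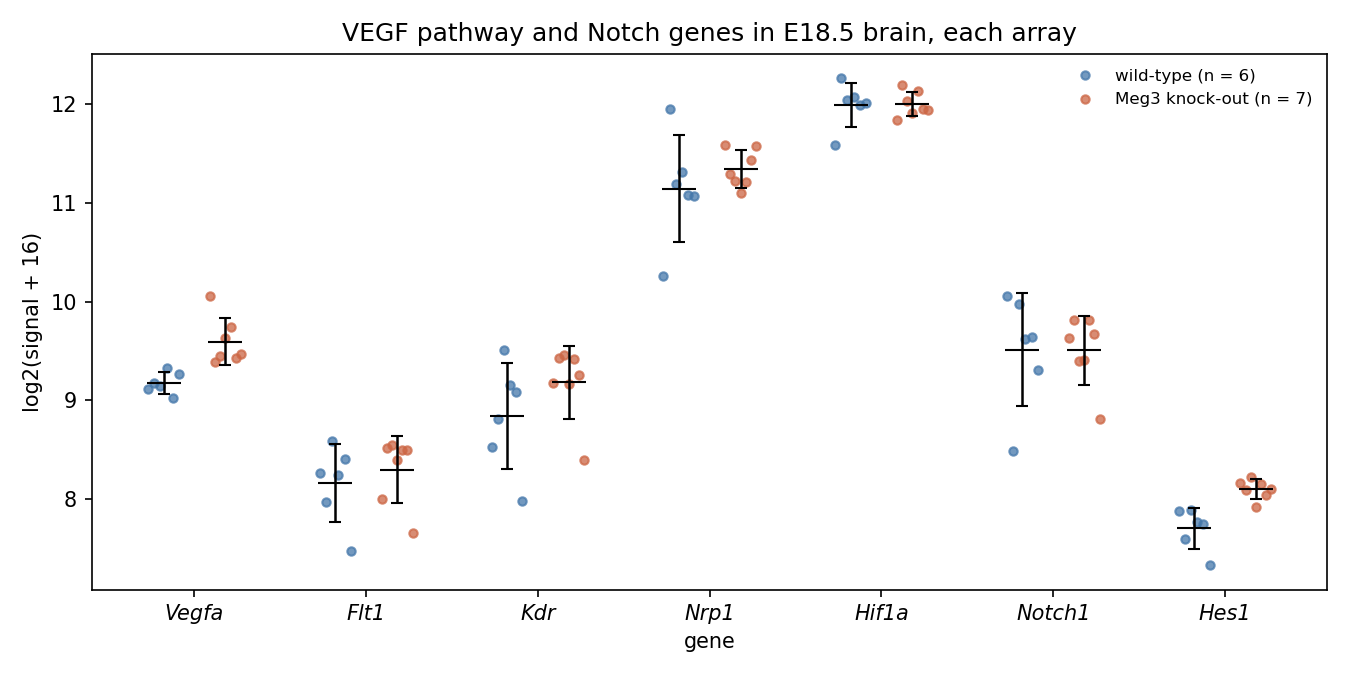
Log2(signal + 16) of Vegfa, its receptors Flt1, Kdr and Nrp1, Hif1a, Notch1 and Hes1 on the vertical axis, 1 point per array for 6 wild-type and 7 Meg3 knock-out brains, with group mean and SD as black bars. Vegfa and Hes1 are higher in all 7 knock-out arrays than in the wild-type arrays, and the others overlap.

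Markers of vessel cells gave no shift. Of 24 endothelial genes 10 had higher and 14 lower means, including Pecam1 at 0.24 ± 0.13 SE and Vwf at 0.38 ± 0.23 SE, both endothelial surface or clotting proteins. The mean of the list was 0.01, its median -0.01 and its camera direction down (adjusted p = 0.473, and 0.995 with an estimated correlation). Without wild-type 6 the list passed, at a mean of -0.06 (adjusted p = 0.0284, and 0.862 with an estimated correlation). Of 13 mural cell genes 8 had higher and 5 lower means, with the pericyte genes Higd1b at 0.23 ± 0.10 SE and Abcc9 at 0.21 ± 0.15 SE (list adjusted p = 0.908). In both lists 0 genes passed over all genes or adjusted over the list alone.

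Genes induced by low oxygen shifted up as a list under the preset correlation. Of 25 tested, 22 had a higher and 3 a lower mean, at a mean log2 change of 0.12, and 0 passed over all genes or adjusted over the list alone. Ldha, lactate dehydrogenase A, had a log2 change of 0.20 ± 0.09 SE and the glycolysis regulator Pfkfb3 of 0.32 ± 0.15 SE. Camera gave an adjusted p of 0.0172, and the adjusted p was 0.855 with an estimated correlation. An exact permutation test of the list's mean gave p = 0.1002, and the list passed in 27 of 37 alternatives. The call ended without wild-type 4 (adjusted p = 0.0742), wild-type 6 (0.143), knock-out 3 (0.0547) or knock-out 4 (0.116), and the mean turned to -0.08 after median centring (0.186), when all genes stood at -0.15. The p53 target list, in which Sesn2 had a log2 change of 0.37 ± 0.17 SE and Pmaip1 of -0.41 ± 0.19 SE, did not pass. Its mean was 0.04, with camera direction down (adjusted p = 0.993), and 12 of 19 genes had higher means. The other Sesn2 probe set had a log2 change of -0.05.

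Genes of S phase and mitosis shifted down as a list under the preset correlation. Of 32 tested, 29 had a lower and 3 a higher mean, with a mean log2 change of -0.12, and 0 passed over all genes or adjusted over the list alone. The mitotic kinases Cdk1 and Aurka had log2 changes of -0.24 ± 0.14 SE and -0.21 ± 0.12 SE. Camera gave an adjusted p of 2.77e-07, and the adjusted p was 0.657 with an estimated correlation. Without knock-out 2, whose list mean was the highest, the mean was -0.21 and the adjusted p with an estimated correlation 0.0312. Without litter 250 the mean was -0.05, the weakest over all settings. In litter 219 the mean of the list was higher in knock-out by 0.54, and it was -0.20, -0.26 and -0.31 in litters 238, 250 and 262. An exact permutation test of the list's mean gave p = 0.389.

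Choroid plexus genes gave the largest shift of any cell type list. Of 8 tested, 7 had a lower and 1 a higher mean, with a mean log2 change of -0.39, and 0 passed over all genes or adjusted over the list alone. Clic6, a chloride channel protein, had a log2 change of -0.84 ± 0.42 SE and Sostdc1, a secreted BMP and Wnt antagonist, of -0.61 ± 0.31 SE. Camera gave an adjusted p of 2.26e-05, and the adjusted p was 0.540 with an estimated correlation. The list mean was lower in knock-out by -0.30, -1.34 and -0.82 in litters 219, 238 and 262 and higher by 0.19 in litter 250 (exact permutation p = 0.228 over all arrays). Single arrays moved the mean, to -0.23 without wild-type 3, -0.25 without knock-out 4 and -0.25 without knock-out 7. Whole litters moved it further and both ways, to -0.17 without litter 238 and -0.64 without litter 250.

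Hes1, a Notch target and repressor of neuronal differentiation, was the Notch list's member with the smallest p. Its signal was 259 ± 18.6 (SD, n = 7) in knock-out and 194 ± 28.9 (SD, n = 6) in wild-type brains, with a log2 change of 0.40 and no overlap between groups (exact permutation p = 0.00117). Over 37 alternatives its log2 change ranged from 0.20 (± 0.14 SE, after median centring) to 0.45, and within litters 219, 238, 250 and 262 it was 0.35, 0.18, 0.34 and 0.78. It did not pass over all genes (limma adjusted p = 1.00), and it passed adjusted over the Notch list alone (0.0419) and over the neural progenitor list alone (0.0219), both of which hold it. These rest on the same unadjusted p, and neither adjustment covers the choice among the 22 lists. Of 23 Notch genes 14 had higher means, with the target Heyl at 0.20 ± 0.13 SE (probe sets from -0.04 to 0.20, list adjusted p = 0.970). Of 16 TGF-beta genes 9 had higher means, with Tgif1 at -0.27 ± 0.12 SE and Tgfb3 at 0.25 ± 0.18 SE. That list's mean was 0.03 and its camera direction down (adjusted p = 0.750).

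Neural and glial markers did not shift in the main comparison. Of 20 neuron genes 13 had higher means, with Syn1 at -0.24 ± 0.14 SE and Dcx at 0.16 ± 0.10 SE (mean 0.04, camera direction down, adjusted p = 0.970). Of 12 neural progenitor genes 8 had higher means, with Eomes of intermediate progenitors at -0.33 ± 0.23 SE (mean 0.01, camera direction down, adjusted p = 0.908). Of 10 astrocyte genes 7 had higher means, with the glutamate transporter Slc1a2 at 0.24 ± 0.17 SE and Gfap at -0.31 ± 0.27 SE (mean 0.04, camera direction down, adjusted p = 0.970). Of 9 oligodendrocyte lineage genes 6 had lower means, with Sox10 at -0.26 ± 0.18 SE and Mag at -0.18 ± 0.16 SE (mean -0.04, adjusted p = 0.158). The Sox10 probe sets ranged from -0.26 to 0.35. Among the alternatives fixed beforehand the oligodendrocyte list passed with litter as a block (0.0154), without wild-type 2 (0.0230) and without knock-out 5 (0.0459). With an estimated correlation it passed in 0 of 37 alternatives (lowest adjusted p = 0.579).

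The lists for other cells and tissues did not pass either. Of 15 microglia and macrophage genes 7 had higher means, led by the receptor Cx3cr1 at 0.31 ± 0.11 SE, with Fcer1g at -0.21 ± 0.17 SE (mean 0.01, median -0.05, camera direction down, adjusted p = 0.750). Of 5 red cell genes 3 had higher means, with the globin Hba-a2 at 0.50 ± 0.19 SE and Bpgm at -0.07 ± 0.10 SE (Bpgm probe sets from -0.07 to 0.16, list adjusted p = 0.908). That list passed without litter 219, at a mean of 0.37 (adjusted p = 0.0299, and 0.549 with an estimated correlation). Of 16 meninges and fibroblast genes 8 had higher means, with Bgn at -0.33 ± 0.29 SE and Fbln1 at 0.19 ± 0.22 SE, 1 of whose probe sets stood at -0.00 (mean -0.01, median 0.01, adjusted p = 0.473), and that list passed without wild-type 6, at a mean of -0.17 (adjusted p = 0.00127, and 0.862 with an estimated correlation). Of 6 muscle, pituitary and retina genes 4 had higher means, with the actins Actc1 at 0.33 ± 0.27 SE and Acta1 at 0.18 ± 0.15 SE (adjusted p = 0.970).

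Imprinting outside the cluster and activity-related genes gave no shift past the threshold. Of 24 other imprinted genes 19 had higher means, with the non-coding RNA Kcnq1ot1 at 0.67 ± 0.31 SE and Dlx5 at -0.26 ± 0.19 SE (mean 0.08, adjusted p = 0.970). Of 9 immediate early genes 5 had lower means, with Egr4 at -0.29 ± 0.16 SE and Junb at 0.31 ± 0.21 SE (mean -0.04, adjusted p = 0.157). Among the alternatives fixed beforehand the immediate early list passed with the 3' to 5' ratio as a covariate (0.0357), and without wild-type 2 (0.0230), knock-out 2 (0.0424), knock-out 6 (0.0429) or litter 250 (0.0471). With an estimated correlation it passed in 0 of 37 (lowest adjusted p = 0.686). Xist, the RNA of the inactive X chromosome, ranged from 47.0 to 13526 among knock-out and from 52.4 to 10590 among wild-type arrays. The sex-linked list, with Xist at 0.67 ± 1.72 SE and the Y-linked Eif2s3y at -0.34 ± 1.23 SE, had a mean of 0.03, a median of -0.10 and camera direction down (adjusted p = 0.750). Within litters 219, 238, 250 and 262 the log2 difference of Xist was 6.84, -7.09, -3.07 and 6.24. That of Eif2s3y was -4.54, 5.02, 2.52 and -5.29. In litters 219, 238 and 262 the genotypes therefore differed in sex, so differences within those litters do not separate genotype from sex. Of all 22 lists, 4 passed with the preset correlation and 1, the imprinted cluster, with an estimated correlation.

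**Figure D3:**
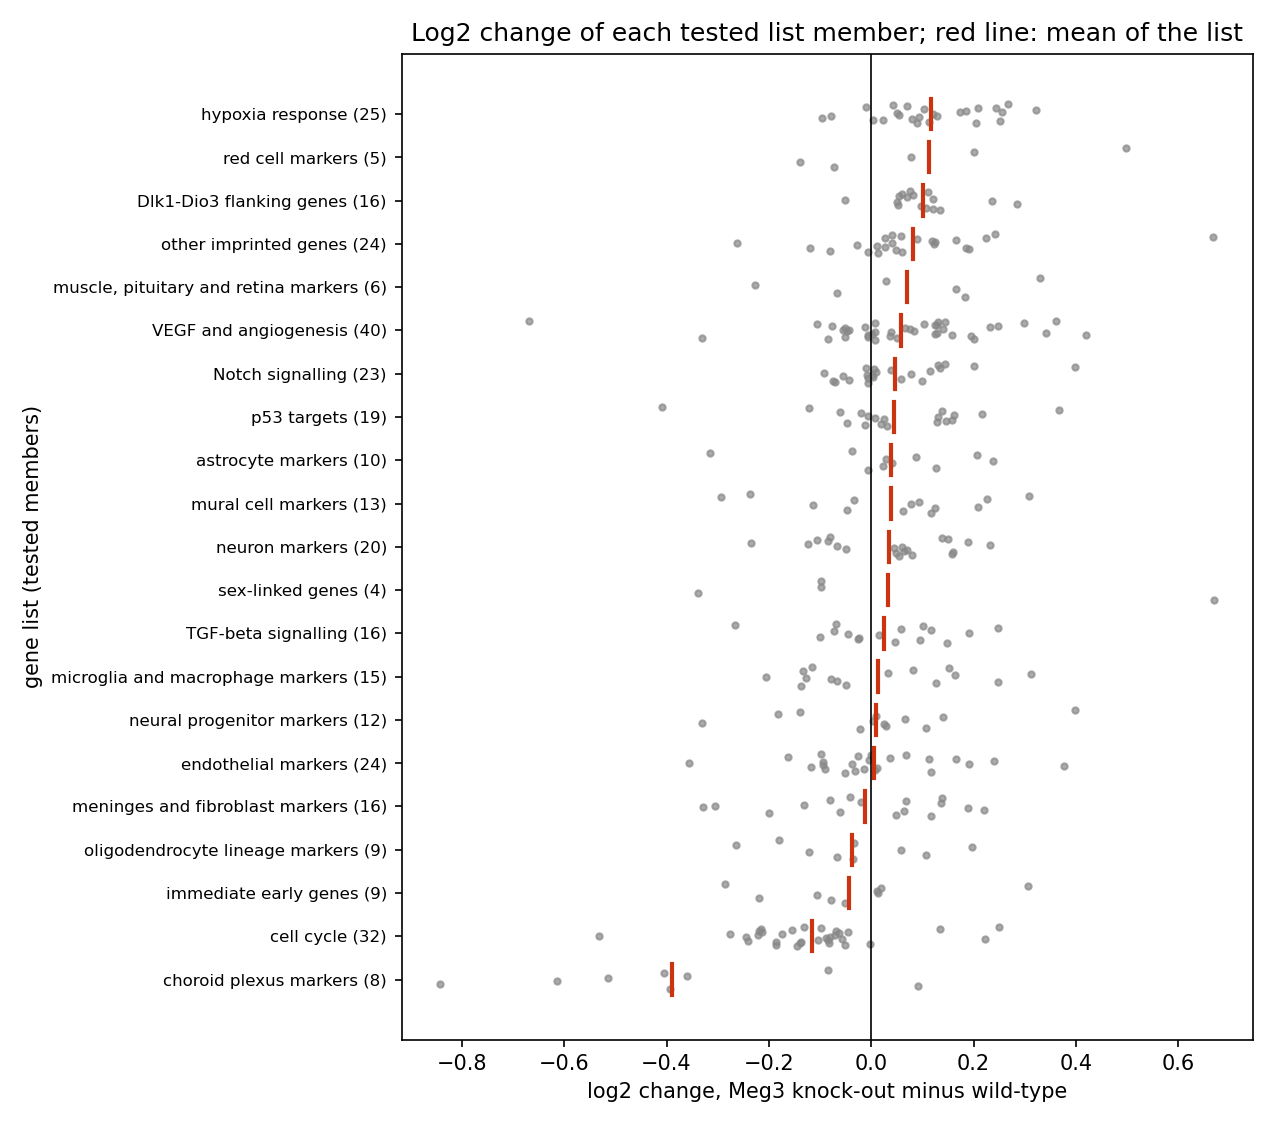
Log2 change, knock-out minus wild-type, of each tested member (grey points, horizontal axis) of the 21 gene lists other than the imprinted cluster, ordered by their mean (red line). The lists' means run from -0.39 for choroid plexus to 0.12 for hypoxia response, and single members of most lists lie on both sides of 0.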

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

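Chosen only after the result was seen were the tests that leave out both arrays of high 3' to 5' ratio, and the bounds by which the estimated correlation, median centring and the 3' to 5' covariate are read here. Those 3 fits themselves and the counts over other splits of the arrays were planned. In 160 groups of arrays, 20 had an array far from the others of its group, where chance gives 8. Each is given as the gap to the nearest array over the range of the group.

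Wild-type 2 and the controls of RNA quality made up several of these. The 3' to 5' ratio of the Actb control was far highest in wild-type 2 (0.859 of the range) and in knock-out 1 (0.763), and that of Gapdh in wild-type 2 (0.822). Wild-type 2 was also far lowest for Rian (0.745), for the mean of the imprinted cluster list (0.692) and for Sesn2 (0.647), and far highest for Rcor1 (0.662). Wild-type 1 was lowest for Dcx (0.634), knock-out 1 for Pecam1 (0.691), and wild-type 3 was highest for Serpina3n (0.729). Knock-out 2 was highest for the cell cycle list (0.587).

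Knock-out 7 stood lowest in 8 of these groups. They were Kdr (0.730), Cx3cr1 (0.634), Notch1 (0.583) and Bgn (0.578), and the list means of hypoxia (0.658), neural progenitors (0.620), Notch signalling (0.582) and VEGF and angiogenesis (0.568). Wild-type 6, from the same litter 262, was far lowest for the endothelial list (0.645). The angiogenesis list had a mean log2 signal of 8.43 in knock-out 7 and 8.44 in wild-type 6. Without knock-out 7 the mean log2 change of that list was 0.12 (camera adjusted p = 0.0755), and over all settings tried its adjusted p ranged from 0.0755 to 0.891. Wild-type 6 also lay below its group mean of 8.73, so leaving it out moves the list's change the other way, down.

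An unnamed probe set outside the gene comparison fell by an amount between those of Mirg and Meg3. Of 2980 probe sets without a gene name, 1 passed, probe set 1431094_at, which fell from 622 ± 131 (SD, n = 6) to 57.6 ± 14.6 (SD, n = 7), a log2 change of -3.11 (limma adjusted p = 1.41e-07).

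The real grouping was set against other splits of the arrays. The 3 genes past the threshold were reached by 1 of 100 drawn splits, the real one, and the highest other split gave 1. The imprinted cluster list was as strong in 1 of 100 splits, with a p of 1.57e-34 against 5.99e-09 for the next. That next split kept 6 of the 7 knock-out arrays together. Meg3 is the deleted gene, and Meg3, Rian and Mirg separate the genotypes without overlap. Both outcomes follow from that separation and add no support of their own. The number of lists past the threshold, 4, was reached in 38 of the 100 splits, with up to 10 in another, so chance is not excluded for that count. At an unadjusted p under 0.05 the other splits had a median of 433 genes and at most 1920, against 255 in the real one, and 25 of them had fewer than the real one.

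The cell cycle, choroid plexus and hypoxia shifts are the first pattern to weigh. Their p was as small in 6, 7 and 8 of the 100 splits, so chance is not excluded. The real p were 2.52e-08, 3.08e-06 and 0.00313, and the smallest among other splits 1.72e-11, 2.20e-10 and 2.78e-05. Those splits had 2, 5 and 6 of the 7 knock-out arrays in the group of 7, so they partly keep the genotype contrast, reversed in the first. Without the 2 arrays of high 3' to 5' ratio the list differences were -0.08 ± 0.15 SE, -0.46 ± 0.35 SE and 0.11 ± 0.08 SE between arrays, against -0.12, -0.39 and 0.12 with all arrays. Camera at its preset correlation still called these lists (adjusted p = 0.00238, 0.000605 and 0.0199), so the calls did not rest on those 2 arrays alone. The smallest difference was 0.528 times its standard error. That cannot decide what part those arrays had, because the spread was wide with all arrays too (exact permutation p = 0.389, 0.228 and 0.1002). With an estimated correlation and all arrays 0 of these lists passed, as genes that vary together between embryos would give. A difference in cell makeup between genotypes stays open too, and so does variation in choroid plexus content between embryos. The neural progenitor (camera adjusted p = 0.908), neuron and astrocyte (0.970 each) lists did not pass. They do not measure how much choroid plexus a sample held, whose list mean ranged from 8.31 in knock-out 4 to 10.3 in wild-type 3.

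Vegfa and Hes1, higher in all 7 knock-out arrays, are the second pattern. As many as 10 genes without overlap occurred in 39 of 100 splits, with up to 69 in another, so chance may account for both genes. These splits ignore litter. Both genes were higher in knock-out within all 4 litters that hold both genotypes, but that follows from the lack of overlap and adds no support. With the 3' to 5' ratio as a covariate the smaller of both changes was 3.58 times its standard error. That ratio stood apart mainly in wild-type 2 and knock-out 1. The fit therefore argues only against those arrays as the whole cause, and it cannot decide on RNA quality in general. After median centring, which moved the median of all genes to -0.15, it was 1.47 times (Hes1 0.20 ± 0.14 SE, Vegfa 0.22 ± 0.12 SE), while Hes1 and Vegfa stood at 0.25 and 0.34 under quantile normalization and at 0.35 and 0.37 with the array factor removed, so part of both changes depends on scaling and it stays open. So does an effect of the Meg3 genotype, beside chance.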

How the results depend on the processing

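Of the alternatives, 4 were chosen after seeing the data: both arrays of high 3' to 5' ratio left out, the same with litter as a block, the array factor removed, and litters 148 and 219 left out. Meg3 stayed past the threshold in 37 of 37 refits, with log2 changes from -4.01 to -3.46, and within litter 238 it was -4.30. The count of lower genes was 3 or 2 in every setting except every probe set on its own. There it was 17 probe sets, because Meg3, Rian and Mirg have several and the unnamed probe set 1431094_at was among them. The count of higher genes was 0 except 1 (Serpina3n) without litter 238, and it ranged from 0 to 1 over the arrays left out in turn. With the replicate block, the numbers of the titles as a block, there were 0 higher and 3 lower genes, Meg3 stood at -3.68 and 4 lists passed. The replicate numbers do not pair embryos, since only 3 of 6 same-numbered pairs had deviations correlated over 0.1 (-0.26 to 0.40). With litter as a fixed block 0 higher and 3 lower genes and 6 lists passed, the flanking and oligodendrocyte lists being added. The number of lists past the threshold was 3 to 6 over the other settings and 1 with an estimated correlation in place of 4. With an estimated correlation it was 1 to 2 over the arrays left out, the second being cell cycle without knock-out 2 (adjusted p = 0.0312). The imprinted list had a mean of -2.10 within litter 219 and -3.17 within litter 238. The direction turned within a litter for hypoxia (-0.0537 in litter 262), cell cycle (0.54 in litter 219) and choroid plexus (0.19 in litter 250). The cause of these moves was not tested. Vegfa stayed higher in 37 of 37 refits (log2 change 0.22 to 0.46) and passed in 0 of them. Signals near the filter of 56.9 limit what weak genes can show.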

Other observations

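The genes in this part were chosen after their values were seen, and so were the tests of other probe sets and of the chromosome segment. The limma comparison was planned, and so were its alternatives, apart from those listed above as chosen after seeing the data.

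Cldn2 and Kcne2 are expressed in choroid plexus but lie outside the fixed list, and being picked by their values they add no support to its shift. Cldn2, a tight junction protein of its epithelium, had a signal of 82.1 ± 49.6 (SD, n = 7) in knock-out and 143 ± 56.8 (SD, n = 6) in wild-type brains, with a log2 change of -0.85 (limma adjusted p = 1.00), while its second probe set had one of 0.16. Kcne2, a potassium channel subunit, had 242 ± 123 (SD, n = 7) against 386 ± 196 (SD, n = 6), with a log2 change of -0.73 (limma adjusted p = 1.00), and a higher value in knock-out in litter 250 (0.24). Malat1, an abundant nuclear non-coding RNA, had a log2 change of 1.65 ± 0.50 SE on the probe set used, and its 7 probe sets ranged from -0.24 to 1.65. On that probe set wild-type 1 had a signal of 66.9 and the other wild-type arrays 471 to 1432, against 1336 to 2703 in knock-out arrays.

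On the log2(signal + 16) scale, the genes with the largest positive and the largest negative change outside the cluster, neither past the threshold, lay on the chromosome that carries Meg3 in GRCm38.p6. Serpina3n had a signal of 185 ± 81.6 (SD, n = 7) in knock-out and 34.2 ± 51.2 (SD, n = 6) in wild-type brains, with a log2 change of 2.29 ± 0.41 SE (limma adjusted p = 0.146, and 0.000416 without wild-type 3, whose signal was 138). Its wild-type signal lay below the filter, so its change depends on the pseudocount, and over all settings it ranged from 1.39 (pseudocount 64) to 3.11 (pseudocount 1), with adjusted p from 0.000416 to 1.00. Galc, the lysosomal galactosylceramidase, had 149 ± 135 (SD, n = 7) against 455 ± 146 (SD, n = 6), with a log2 change of -1.95 ± 0.50 SE (limma adjusted p = 1.00). Between Galc and Serpina3n lay 36 tested genes, and 25 between Serpina3n and Meg3.

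A candidate explanation for Galc is a failure of 1 probe set, such as a sequence variant under it, since the lowest log2 change of its other probe sets was 0.18. Those probe sets are weaker, at wild-type signals of 94.2 and, below the filter, 9.85, so they test this poorly. Its signal was 31.8 to 61.1 in knock-out 4 to 7, 287 to 304 in knock-out 1 to 3, 256 and 292 in wild-type 3 and 4, and 480 to 602 in the other wild-type arrays, so the middle level occurred in both genotypes. Serpina3n has 1 probe set, so the same explanation cannot be told apart from a change in its RNA. A segment of chromosome carried along with the targeted allele may hold such variants or expression differences. Among 100 tested genes around Meg3, with the cluster, Serpina3n and Galc left out, 1 had an unadjusted p under 0.05, against a median of 2 per 100 neighbouring genes on other chromosomes, which neither shows nor excludes it. The window was placed around Meg3, so it covered the 25 tested genes between Serpina3n and Meg3. It need not cover all of the 36 between Galc and Serpina3n.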
